A study of Rattus norvegicus with 24 samples.

How the data were processed

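Poly(A) RNA was sequenced from 24 samples of rat INS1 cells, an insulinoma line used as a model of the pancreatic beta cell, that carry a doxycycline-inducible mouse IRE1α transgene. The deposited table holds raw read counts per Ensembl gene ID, made by the authors without normalization. Libraries were prepared from poly(A)-enriched RNA with a NEBNext Ultra II kit, per the labels' protocols. HISAT2 and HTSeq were named with no version or setting, per the submitters' processing notes. The genome build, annotation release and strand setting were not given in the sources used here, so reads of overlapping, antisense or near-identical genes may not have been kept apart.

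The table held 26689 IDs, of which 6523 had no count in any library. Library totals ran from 12.6 to 23.8 M counts, so that 3 counts, the limit that a count of 0 allows, corresponded to 0.126 to 0.238 CPM (counts per 1 M counts) depending on the library. These limits cover counting error only, since reads amplified by PCR are not independent molecules. Every column was assigned to a sample by its name and the sample's title.

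The files do not pair the IDs with gene names, and 0 of the 26689 IDs matched the gene table used for names. The 22 gene lists fixed before the data were examined, among them targets of spliced XBP1, substrates of IRE1α-dependent decay and insulin granule genes, could therefore not be tested, and the markers of other islet, exocrine and stromal cells could not be read. The transgene and the endogenous Ern1 gene were not analysed by name here, so the labels were not checked against the level of the induced gene. For the same reason at most 2 IDs that rose and 2 that fell are printed. The rule for naming them, fixed beforehand, took for each of 8 comparisons up to 5 IDs per direction with the largest fold change among those called, with a mean of at least 5 CPM in the higher group and no overlap between the 3 and 3 libraries. It gave 79 picks, of which 19 came from IDs with an over 8-fold spread inside one of the compared groups. Its condition on gene symbols could not be applied. Of the 4 IDs printed, 3 were taken from these picks after their values had been seen, and ENSRNOG00000012052, which had the rank 2 in total count, lies outside the rule and was also chosen after its values were seen.

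Groups were taken from the sample titles, which give the treatment, the time and a replicate number. For 6 libraries, those induced and given vehicle, the time characteristic contradicts the title, the description and the column name. The title was used, and the other assignment was computed as an alternative.

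Counts were tested with edgeR 4.0.16 in R 4.3.3. IDs were kept with filterByExpr over the 8 groups at a minimum count of 10, which left 13760 IDs and dropped 12929. The kept IDs held at least 99.9% of each library's counts. Libraries were scaled by TMM, 1 quasi-likelihood model with a mean for each group was fitted to all 24 libraries, and each contrast was adjusted by the Benjamini-Hochberg method over the 13760 IDs. An ID was called at an adjusted p below 0.05, and every adjusted p and standard error (SE) of a fold change in the text comes from this test unless another tool is named. No replicate block was used. Group levels are given as TMM-scaled CPM, mean ± SD over the 3 libraries of a group. Nothing in the labels says whether the replicates of a group came from separate cultures on separate days, so p-values measure only the spread between these samples, which can be technical. No replicate pair agreed within sampling noise: the chi-square per degree of freedom between replicates ran from 3.63 to 19.5.

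The place of each 24 h library between the uninduced and the induced libraries was computed over the IDs called for induction at 24 h, raised and lowered separately, as the slope of its log2 CPM difference from the uninduced mean on the induced difference, in percent. This measure was chosen after the data had been examined. An induction score, planned beforehand, was the mean log2 CPM of the IDs that rose with induction minus that of the IDs that fell, with the IDs taken from the other time point. Scores were compared by exact two-sided permutation tests, which with 3 against 3 libraries cannot go below p = 0.1. Calls shared by both compounds against the same induced libraries were set beside 10 simulations of unchanged compound groups and beside the overlap of independent lists. The IDs moved back by a compound were set beside the same simulations, a step added after the counts had been seen.

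The procedure was tested on simulated data after the first run on the real counts and was not changed by it, with counts drawn at the real means, library sizes and gene-wise spread for PAIR1 against induced libraries at 4 h and 200 of 13760 IDs changed, all with a mean of at least 1 CPM. Over 5 simulations it recovered 64.2% of the IDs changed by 0.5 on the log2 scale and 86.0% of those changed by 1, and 3.96% of all calls were false.

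The alternatives fixed before the data were examined were DESeq2 1.42.0 in place of edgeR, RLE in place of TMM size factors, no filter, a stricter filter with a minimum count of 50, a fit of the compared libraries alone, a replicate block, the other time label for the 6 libraries, and the omission of each library in turn. An adjusted p that DESeq2 left out stayed out of the counts. A set of 6 libraries found to share a block of IDs, used as a covariate or left out, was added after seeing the data, as were the alternatives for the percent of the induction change and, apart from an adjusted p below 0.01, those for the shared calls. Figures were drawn with matplotlib 3.10.9.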

Results

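RNA was measured in INS1 cells under 4 treatments at 4 h and 24 h after induction, with 3 libraries in each of the 8 groups. Uninduced cells received vehicle and no doxycycline. Induced cells received doxycycline, which switches on IRE1α, the endoplasmic reticulum stress sensor with a kinase and an RNase domain, together with vehicle or with PAIR1 or KIRA9, 2 compounds that the series describes as modulators of the IRE1α kinase. The doses of the compounds are not stated in the labels. Mean library totals were 17.0 ± 3.2 M counts (SD, n = 3) for uninduced cells at 4 h, 17.5 ± 2.9 for induced cells at 4 h, 16.5 ± 2.2 for PAIR1 at 4 h, 15.7 ± 1.1 for KIRA9 at 4 h, 19.2 ± 4.1 for uninduced cells at 24 h, 16.2 ± 3.1 for induced cells at 24 h, 15.3 ± 2.7 for PAIR1 at 24 h and 17.0 ± 3.0 for KIRA9 at 24 h.

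The first comparison asked what induction of IRE1α changed. At 4 h it changed few IDs: 5 of 13760 rose and 36 fell. At 24 h 4102 IDs rose and 4401 fell, and the falls were deeper, with 1257 IDs at least 2-fold lower against 387 at least 2-fold higher. The median called change at 24 h was 0.42 on the log2 scale among IDs that rose and -0.65 among those that fell. The called IDs were 61.8% of those tested, whereas TMM scaling takes most IDs as unchanged. Rises and falls are therefore relative to the other IDs, and their balance depends in part on the scaling. Of the IDs called at 4 h, 4 of the 5 that rose and 35 of the 36 that fell were called in the same direction at 24 h, where independent lists of these lengths would share 1.49 and 11.5.

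ENSRNOG00000012864 rose from 113 ± 4.7 to 785 ± 35 CPM (SD, n = 3) at 4 h, by 2.79 ± 0.05 (SE) on the log2 scale with an adjusted p of 1.5e-20 in edgeR's quasi-likelihood test, and from 104 ± 7.6 to 985 ± 35 CPM at 24 h (log2 change 3.24 ± 0.05, adjusted p = 4.3e-23). ENSRNOG00000004089 stood at 91.8 ± 2.4 CPM in uninduced and 77.7 ± 2.3 in induced cells at 4 h, which was not called, and fell from 111 ± 17 to 7.06 ± 1.64 CPM at 24 h (log2 change -4.00 ± 0.11, adjusted p = 7.5e-19). ENSRNOG00000012052 was among the most abundant transcripts, at 1.76 ± 0.28% of counts in uninduced cells at 24 h, and fell to 0.672 ± 0.024% with induction, a log2 change of -1.53 ± 0.08 with an adjusted p of 8.8e-14. At 4 h its share was 2.14 ± 0.12% without and 2.24 ± 0.16% with induction. The share of counts taken by the 10 most abundant IDs of a library was 8.54 ± 0.14% in uninduced and 6.73 ± 0.11% in induced cells at 24 h.

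Uninduced cells received no doxycycline, so these contrasts hold the effect of doxycycline itself together with that of the transgene. The count at 4 h moved with the method, to 70 calls with DESeq2 and 27 when only the 6 compared libraries were fitted. With the times of the 6 induced vehicle libraries taken from the conflicting time characteristic, 8700 IDs were called at 4 h and 3787 at 24 h.

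**Figure D1:**
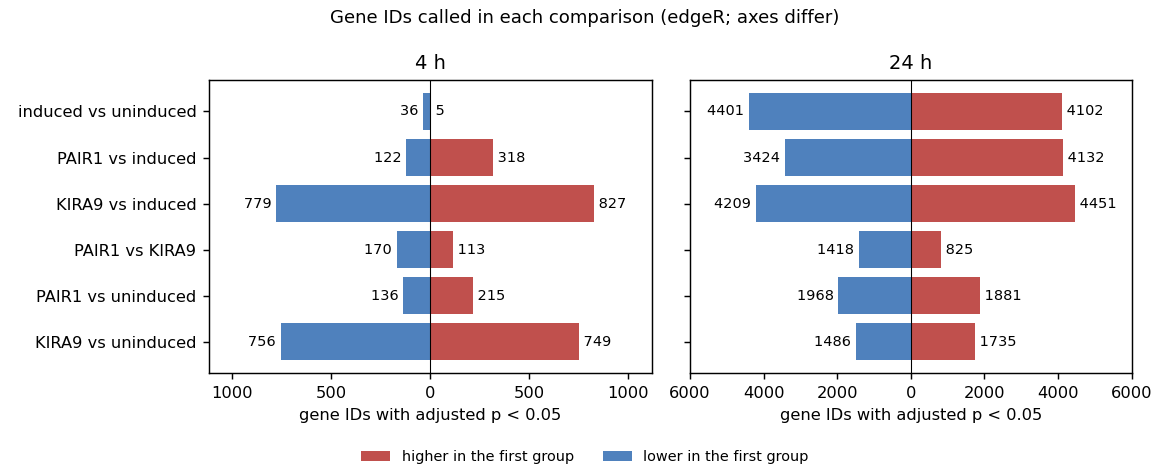
Number of gene IDs called by edgeR's quasi-likelihood test in each comparison at 4 h (left) and 24 h (right), with IDs higher in the first-named group to the right of 0 and IDs lower to the left; the 2 horizontal axes differ in scale. Induction called 41 IDs at 4 h and 8503 at 24 h.

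The next comparisons asked how far each compound kept induced cells from the induced state at 24 h. Both moved most of the changed IDs back. Of the 4102 IDs raised by induction, 2875 were lower with PAIR1 than with vehicle and 3302 were lower with KIRA9. Of the 4401 lowered by induction, 3632 were higher with PAIR1 and 3833 were higher with KIRA9. These counts compare both compounds with the same induced libraries that helped to choose the IDs. In 10 simulations with the compound groups at the induced level at most 1 ID moved back in any of them. The simulations took the observed group means as true, so they do not measure all that this choice can add. In all, PAIR1 differed from induced vehicle cells in 7556 IDs (4132 higher, 3424 lower) and KIRA9 in 8660 (4451 higher, 4209 lower).

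Neither compound brought the cells to the uninduced profile. The PAIR1 libraries retained 36.4 ± 2.0% (SD, n = 3) of the induction change over the raised IDs and 34.1 ± 1.0% over the lowered IDs, and the KIRA9 libraries retained 18.3 ± 1.1% and 9.35 ± 0.26%. Simulated libraries drawn at the uninduced level gave means of 6.81% over raised and 2.56% over lowered IDs, since the same uninduced libraries had helped to choose the IDs. Against uninduced cells, 3849 IDs were called with PAIR1 (1881 higher, 1968 lower) and 3221 with KIRA9 (1735 higher, 1486 lower). Among the IDs raised by induction and moved back, 791 were still above the uninduced level with PAIR1 and 460 with KIRA9, and 67 and 279 had passed below it. Among those lowered and moved back, 1332 were still below with PAIR1 and 558 with KIRA9, and 237 and 617 had passed above it.

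ENSRNOG00000012052 was at 1.59 ± 0.11% of counts with PAIR1 and 1.73 ± 0.02% with KIRA9 at 24 h, and neither was called against uninduced cells (adjusted p = 0.11 and 0.87). The result for PAIR1 depended on single libraries: the log2 change from uninduced cells was -0.17 with all libraries, -0.30 without uninduced replicate 1 (adjusted p = 0.00030) and -0.23 without PAIR1 replicate 3 (adjusted p = 0.049). ENSRNOG00000004089 was restored in part, to 22.5 ± 1.3 CPM with PAIR1 and 57.5 ± 2.0 with KIRA9. ENSRNOG00000012864 moved the other way with PAIR1, to 1277 ± 62 CPM, which was 0.37 ± 0.05 (SE, log2) above induced cells with an adjusted p of 4.6e-07, and was 756 ± 33 CPM with KIRA9, still 7.26-fold above uninduced cells.

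A score built from the IDs called at 4 h, which shares no library with the scored ones, placed the 24 h groups in the same order. It was 1.45 ± 0.04 log2 units in induced, 0.78 ± 0.09 in PAIR1, -0.29 ± 0.06 in KIRA9 and -2.12 ± 0.08 in uninduced libraries (SD, n = 3). The distance above uninduced libraries was 3.57 in induced, 2.89 in PAIR1 and 1.82 in KIRA9 libraries. Relative to the induction difference, this planned score thus put both compounds nearer to the induced libraries than the percents retained did. The groups did not overlap, and the exact permutation p of each of the 6 pairs was 0.1, the smallest that 3 against 3 libraries allow (0.13 after adjustment over 12 pairs at both times). The difference between PAIR1 and KIRA9, 1.07, was 0.61 without the filter on low counts, 0.67 with only the compared groups fitted and 0.27 with the other time label. Only 5 IDs that rose at 4 h enter it, 9 without the filter and 4 in the compared groups alone. Of the 5, 1 was ENSRNOG00000012864, which stayed 3.62 log2 units above uninduced cells with PAIR1 and 2.86 with KIRA9 at 24 h. A single ID weighs heavily in a mean over so few. At 4 h, with the IDs called at 24 h, the score was -0.39 in induced, -0.43 in PAIR1, -0.44 in KIRA9 and -0.43 in uninduced libraries, and the difference between PAIR1 and KIRA9 was 0.01 (exact permutation p = 0.2, adjusted p = 0.24).

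**Figure D2:**
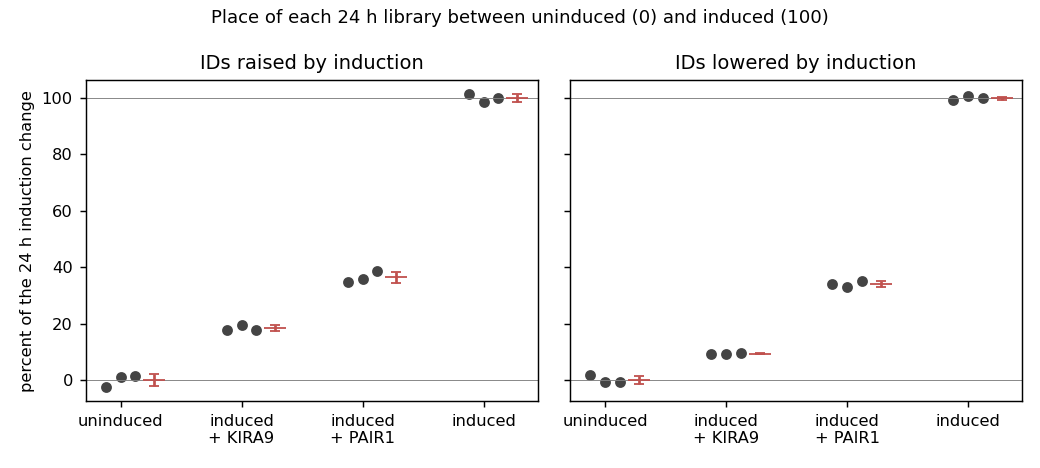
Place of each 24 h library between the uninduced mean (0) and the induced mean (100), in percent of the induction change (vertical axis), for IDs raised (left) and lowered (right) by induction; points are libraries, red marks are the mean ± SD of 3. The PAIR1 libraries averaged 36.4% and 34.1%, the KIRA9 libraries 18.3% and 9.35%.

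At 4 h, when induction had changed 41 IDs, the compounds changed more. PAIR1 raised 318 and lowered 122 IDs relative to induced vehicle cells, and KIRA9 raised 827 and lowered 779. ENSRNOG00000001859 showed it without an induction effect at that time: it stood at 95.2 ± 1.3 CPM in uninduced and 89.6 ± 6.5 in induced cells, and rose to 197 ± 7.0 CPM with PAIR1 (log2 change 1.13 ± 0.06 SE, adjusted p = 5.2e-12) and to 354 ± 11 with KIRA9 (1.98 ± 0.06, adjusted p = 5.7e-17). ENSRNOG00000012864 fell from 785 CPM with vehicle to 647 ± 21 with PAIR1 and 403 ± 1.4 with KIRA9. Against uninduced cells, 351 IDs were called with PAIR1 (215 higher, 136 lower) and 1505 with KIRA9 (749 higher, 756 lower). Among the 36 IDs lowered by induction at 4 h, 29 were higher with PAIR1 than with vehicle and 31 were higher with KIRA9, against at most 1 in the simulations without a compound effect. Of the 31, 10 had passed above the uninduced level with KIRA9, and of the 29 none had with PAIR1. Among the 5 IDs raised at 4 h, 1 was lower with PAIR1 and 3 were lower with KIRA9, of which 2 had passed below the uninduced level. The simulations took the observed group means as true, and called on average 71.7 lowered and 38.9 raised IDs for induction at 4 h. They therefore do not measure all that the shared induced libraries can add to the counts of IDs moved back.

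No uninduced cells were given a compound, so effects of the compounds that do not pass through induced IRE1α are not separated. Several PAIR1 counts at 4 h moved when 1 library was left out: against induced cells the count was 269 without PAIR1 replicate 2, 244 without PAIR1 replicate 3, 290 without induced replicate 2 and 292 without induced replicate 3, and 280 when only the 6 compared libraries were fitted. Against uninduced cells it was 196 to 231 with any 1 of the 6 libraries left out and 198 when these libraries were fitted alone. Against uninduced cells at 24 h, KIRA9 changed 2070 IDs when only the compared libraries were fitted.

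The IDs changed by both compounds relative to induced vehicle cells numbered 283 raised and 108 lowered at 4 h, with 0 in opposite directions, and 3854 raised and 3149 lowered at 24 h, with 8 in opposite directions. Independent lists of these lengths would share 19.1 and 6.91 IDs at 4 h and 1337 and 1047 at 24 h. Both comparisons use the same 3 induced libraries, and in 10 simulations of unchanged compound groups against them no shared call was made. Groups simulated without a compound effect leave little to share, so this is no reference for compounds that each change many IDs. Across IDs, which are not independent replicates, the fold changes of both compounds correlated with r = 0.69 at 4 h and 0.86 at 24 h, against 0.49 and 0.50 in the simulations, and their covariance was 0.0922 and 0.355 against 0.0324 and 0.0333. The simulated values already hold what shared controls add under the fitted spread, so the excess lies beyond that part. The 3 induced libraries are too few to be split into parts of at least 2 libraries, so any further part from the shared controls was not measured. Counts with separate controls at 4 h are given under the other observations. The number shared against induced cells at 4 h was 251 without PAIR1 replicate 2, 227 without PAIR1 replicate 3, and 197 at an adjusted p below 0.01.

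**Figure D3:**
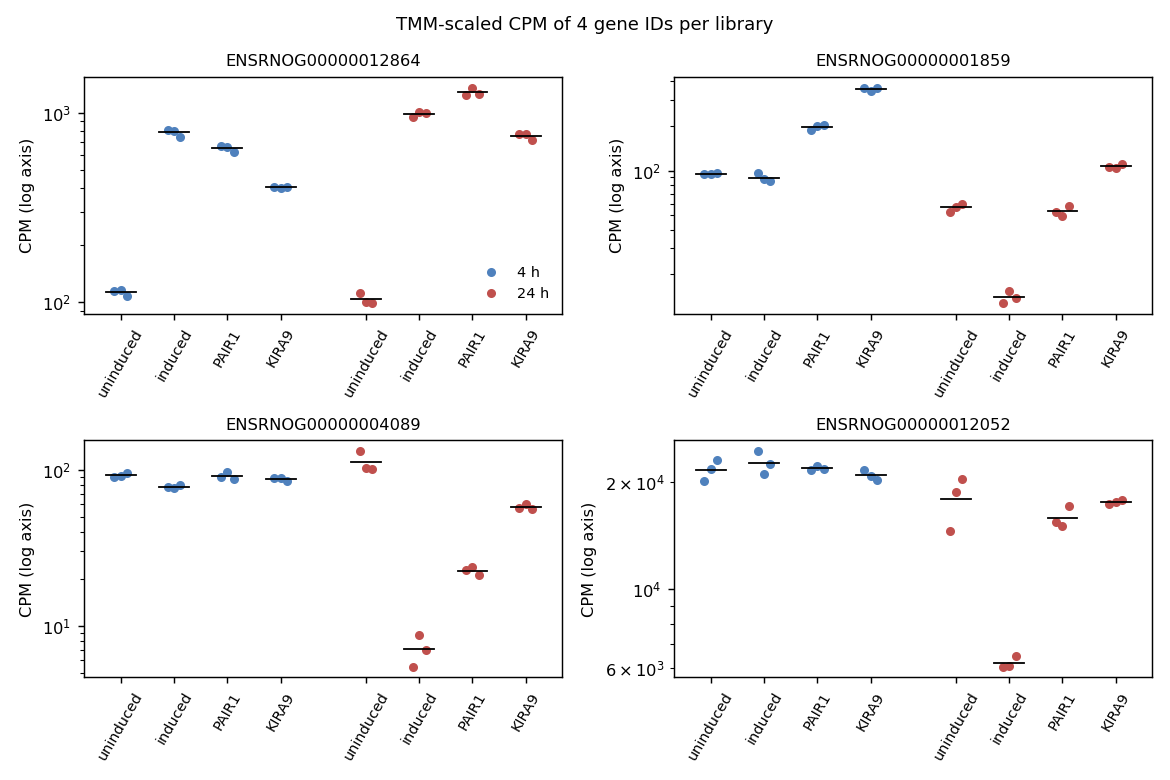
TMM-scaled CPM (vertical log axis) of 4 gene IDs in each library, grouped by treatment, at 4 h (blue) and 24 h (red); bars are group means of 3 libraries, and PAIR1 and KIRA9 denote induced cells given the compound. ENSRNOG00000004089 averaged 7.06 CPM in induced and 111 in uninduced cells at 24 h.

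The direct comparison of PAIR1 with KIRA9 asked whether the compounds left induced cells in different states. At 24 h 825 IDs were higher and 1418 lower with PAIR1, and 2010 of these 2243 were IDs that induction changed. Among those raised by induction, 633 were higher with PAIR1 than with KIRA9 and 29 were lower. Among those lowered by induction, 1305 were lower with PAIR1 and 43 were higher. Of all 2243, the PAIR1 mean lay further than the KIRA9 mean, on the same side, from the uninduced mean in 899, the KIRA9 mean lay further in 362, and in 982 the compounds lay on opposite sides. This contrast shares no library with the one that chose the induction IDs. The median difference, PAIR1 minus KIRA9, was 0.21 on the log2 scale among the 825 IDs called higher and -0.33 among the 1418 called lower, and 0.09 over all IDs raised by induction and -0.11 over all lowered, most of which were not called. The percent of the induction change retained differed by 18.03 percentage points over raised and 24.7 over lowered IDs (exact permutation p = 0.1 for each, the smallest possible), and all 3 PAIR1 libraries lay above all 3 KIRA9 libraries.

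Single IDs differed in how they followed this order. ENSRNOG00000004089 was lower with PAIR1 than with KIRA9 at 24 h by a log2 change of -1.35 ± 0.10 (adjusted p = 4.4e-10). ENSRNOG00000001859, at 56.4 ± 3.2 CPM in uninduced and 14.1 ± 1.4 in induced cells at 24 h, was at 53.4 ± 3.9 with PAIR1 and 107 ± 3.8 with KIRA9, so that only the KIRA9 level differed from uninduced cells by the test (log2 change 0.92 ± 0.06, adjusted p = 3.7e-11; PAIR1 -0.08 ± 0.06, adjusted p = 0.39). For ENSRNOG00000012052 the difference between the compounds was -0.15 ± 0.08 and was not called (adjusted p = 0.22), though it was when only the 6 compared libraries were fitted (adjusted p = 0.026).

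At 4 h 113 IDs were higher and 170 lower with PAIR1 than with KIRA9, and 7 of these 283 had been changed by induction. In 223 of the 283 the KIRA9 mean lay further than the PAIR1 mean, on the same side, from the mean of both vehicle groups, the PAIR1 mean lay further in 1, and in 59 the compounds lay on opposite sides. ENSRNOG00000001859 was lower with PAIR1 than with KIRA9 by a log2 change of -0.84 ± 0.06 (adjusted p = 6.2e-10), and ENSRNOG00000012864 was higher by 0.68 ± 0.05 (adjusted p = 1.5e-09). The count was 187 without PAIR1 replicate 1. The number of induction IDs among the calls was 4 without PAIR1 replicate 2 or 3 or without KIRA9 replicate 1 or 2, and 11 with DESeq2. Because the doses are not given, these differences compare the treatments as applied, not the compounds at equal dose.

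**Figure D4:**
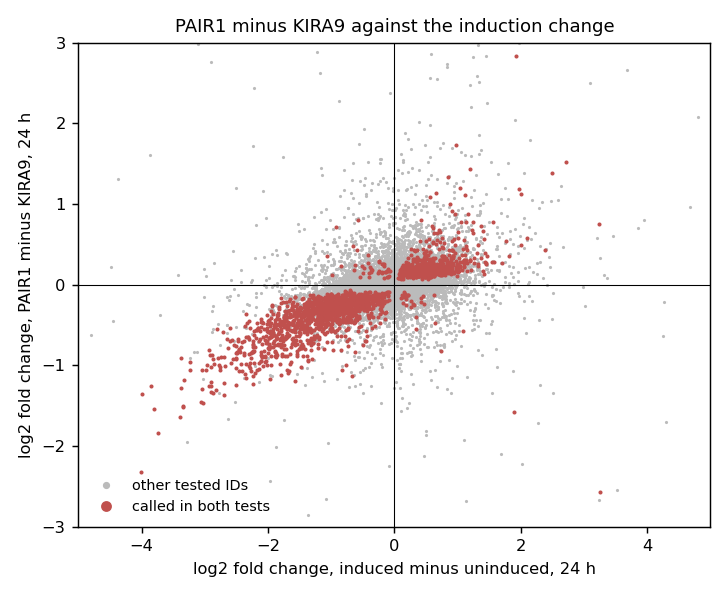
Log2 fold change of PAIR1 minus KIRA9 at 24 h (vertical axis) against that of induced minus uninduced cells at 24 h (horizontal axis), 1 point per tested ID; red points are the 2010 IDs called in both tests, and 33 IDs lie outside the axes. Most red points lie where both changes have the same sign, 633 among raised and 1305 among lowered IDs.

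The differences between times were tested directly. The induction effect differed between 24 h and 4 h in 6918 IDs, being more positive at 24 h in 3094 and more negative in 3824. For ENSRNOG00000004089 the induction effect was lower at 24 h by a log2 change of -3.76 ± 0.14 (adjusted p = 6.0e-16), and for ENSRNOG00000012864 it was higher by 0.45 ± 0.07 (adjusted p = 6.9e-06). The difference between PAIR1 and KIRA9 changed with time in 1185 IDs, becoming more positive in 297 and more negative in 888. Between 4 h and 24 h 3739 IDs changed in uninduced cells, 8581 in induced cells, 4726 with PAIR1 and 4070 with KIRA9.

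A block of 29 IDs, chosen because they were higher in each of 6 libraries than in any other, split the libraries across the treatments. It held 0.604 to 0.680% of counts in 6 libraries and 0.0411 to 0.0563% in the other 18. The 6 were PAIR1 at 24 h replicate 1, induced at 24 h replicates 1 and 2, induced at 4 h replicate 3, uninduced at 24 h replicate 2 and uninduced at 4 h replicate 2, and 0 were KIRA9 libraries. Of 49 IDs that were higher in these 6 libraries by a test chosen after the set was seen, 32 were called for KIRA9 against induced cells at 24 h, where 2 of the 3 induced libraries and no KIRA9 library belong to the set, and at most 5 in any other contrast. With these 6 libraries left out, 246 IDs were called at 4 h for PAIR1 and 966 for KIRA9 against induced cells, 161 for PAIR1 and 944 for KIRA9 against uninduced cells, and at 24 h 6693 for induction, 5540 for PAIR1 and 7044 for KIRA9 against induced cells, and 1741 for PAIR1 against KIRA9. The induced group at 24 h then holds 1 library, replicate 3, which is assumed to vary like the libraries of the other groups.

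**Figure D5:**
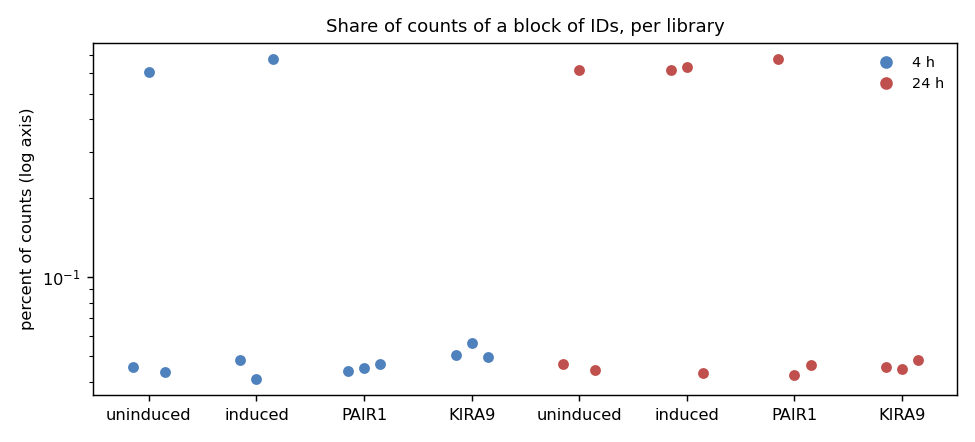
Percent of all counts (vertical log axis) taken by a block of 29 IDs in each library, by treatment, at 4 h (blue) and 24 h (red). In 6 libraries of 5 groups the share was 0.604 to 0.680%, and in the other 18 it was at most 0.0563%.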

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

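The tests of differences between times were planned, and the tests of explanations in this part were chosen after the results had been seen. Both differences between times stood out because the same contrast gave different effects at 4 h and at 24 h. The induction effect differed in 6918 IDs and the difference between PAIR1 and KIRA9 in 1185. Group labels were then exchanged within each time. For induction by time, 14 of 100 splits drawn from 200, the real one included, called as many IDs, with 7153 as the highest of the others. All 13 others among them had left the 24 h groups whole, and drawn splits that broke them called at most 32. For PAIR1 against KIRA9 by time, 6 of 100 drawn splits called as many, the highest of the others being 1908. All 5 others among them had left the 24 h groups whole, while 3 further splits of that kind called fewer IDs than the real one, and drawn splits that broke them called at most 67. High counts were thus seen only among drawn splits that kept the 24 h groups whole, in all 13 of these for induction and in 5 of 8 for PAIR1 against KIRA9. Such splits keep the difference at 24 h whatever the labels at 4 h. Neither count of splits can therefore decide whether the difference between times arose by chance.

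The contrasts within a time compare 3 with 3 libraries, whose 10 splits are too few for a share below 0.05. In each of them 1 split, the real one, gave as many calls. Every other split mixes libraries of both groups, which raises the spread within its groups wherever the real groups differ. Low counts in the other splits are therefore no measure of what chance alone would give. At 4 h the real and the highest other count were 41 and 1 for induced against uninduced cells, 440 and 1 for PAIR1 and 1606 and 1 for KIRA9 against induced cells, 283 and 1 for PAIR1 against KIRA9, and 351 and 1 for PAIR1 and 1505 and 0 for KIRA9 against uninduced cells. At 24 h they were, in the same order, 8503 and 0, 7556 and 0, 8660 and 1, 2243 and 0, 3849 and 2, and 3221 and 1. For induction IDs that differed between PAIR1 and KIRA9 they were 7 and 0 at 4 h and 2010 and 0 at 24 h.

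The PAIR1 libraries lay between the KIRA9 and the induced libraries at 24 h. A single library does not account for this, since the lowest PAIR1 library lay 15.1 percentage points above the highest KIRA9 library over raised IDs and 23.4 over lowered IDs. An error of scaling would shift raised and lowered IDs alike, whereas the median of PAIR1 minus KIRA9 was 0.20 log2 units higher in raised than in lowered IDs, and 0.18 to 0.21 in each of the 9 pairs of libraries. A mixture in which some PAIR1 cells stayed wholly induced stays open. In 23.2% of 1225 strongly changed IDs all 3 libraries lay over 25 percentage points from the median share of 39.1%, against at most 1.14% in 20 simulated mixtures, but these assumed that the other cells were at the uninduced level, which was not measured. A partial block of IRE1α by PAIR1, a difference in effective dose and other targets of the compounds were not tested.

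The times of the 6 induced vehicle libraries conflict between labels. On the scale of the change between uninduced cells at 4 h (0%) and at 24 h (100%), over 3739 IDs, the 3 libraries titled 4 h lay at 12.5 to 15.7% and the 3 titled 24 h at 48.1 to 51.4%. The PAIR1 and KIRA9 libraries, whose labels do not conflict, lay at up to 17.99% at 4 h and from 52.8% at 24 h. The titled times thus fall on the side of the midpoint, 35.4%, that an exchange of the titles would forbid, which is a check from the data and not a label. The reference to the compound libraries replaced a first bound of 50% after the values had been seen and that bound had left the test undecided, because 24 h libraries given a compound themselves averaged 56.1% and 56.3%.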

How the results depend on the processing

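The replicate block, fitted within each time, moved no count of calls by over 1.5 times and ended no call of a printed ID: for example 45 IDs were called for induction at 4 h and 8518 at 24 h with it. The numbers showed no clear pairing of the samples. Of 36 same-numbered pairs, 10 deviated together with a correlation over 0.1 (range -0.336 to 0.383). The median correlation was -0.00094 over same-numbered and -0.0041 over differently numbered pairs, and 10 of the 24 libraries correlated best with their own number. The highest correlation, 0.561, joined differently numbered libraries of the set of 6. That set can hide a pairing, so none is excluded. Tests of the 22 gene lists and all their alternatives were not run, because the IDs could not be matched to names. No contrast's median over all IDs moved beyond 0.1 log2 under any alternative other than leaving out a library, for which it was not computed. Each of these alternatives scales the libraries so that the fold changes centre near 0, so the medians do not test the scaling itself.

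Counts are given here where they moved by over 1.5 times and percents and scores where they moved beyond the SD between replicates. The causes were not tested, apart from the smaller number of libraries that some settings leave by construction. DESeq2 called 70 IDs for induction at 4 h and 11 induction IDs between PAIR1 and KIRA9 at 4 h. Fitting only the compared groups called 27 for induction at 4 h, 280 for PAIR1 against induced and 198 for PAIR1 against uninduced cells at 4 h, 2070 for KIRA9 against uninduced cells at 24 h, and 255 shared by both compounds at 4 h. An adjusted p below 0.01 left 197 shared at 4 h. The score difference between PAIR1 and KIRA9 at 24 h was 0.61 without the filter, 0.67 in the compared groups alone, 0.84 with DESeq2, 0.85 with the block as covariate and 0.27 with the other time label.

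Exchanging the times of the 6 induced vehicle libraries called, at 4 h, 8700 IDs for induction, 8733 for PAIR1 and 8939 for KIRA9 against induced cells, 244 induction IDs between the compounds and 7976 shared, and at 24 h 3787, 4646, 4218, 1024 and 2673. The percent of induction retained became 49.3 and 50.6 over raised IDs and 52.7 and 47.9 over lowered IDs for PAIR1 and KIRA9. It reversed ENSRNOG00000012052 to log2 changes of -1.80, 1.82 and 1.75 for induction, PAIR1 and KIRA9 at 4 h and 0.34, -0.51 and -0.36 at 24 h, ENSRNOG00000001859 to 0.67 for induction and -0.75 for PAIR1 at 24 h, and ENSRNOG00000004089 to -1.79 for PAIR1 and -0.43 for KIRA9 at 24 h. It reversed the induction by time of ENSRNOG00000012864 to -0.20, ENSRNOG00000001859 to 3.44, ENSRNOG00000004089 to 3.21 and ENSRNOG00000012052 to 2.14. Of 860 values of the printed IDs over 14 contrasts, 835 kept their side of the threshold without a reversal, 14 reversed, 10 gained and 1 lost the call. A change of sign was counted as a reversal only where either value was called, so uncalled values among the 835 may have changed sign. Of those that changed, 6 gained calls came from other settings, the fit of the compared groups alone, added for single IDs after seeing the data, or a library left out.

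With the 6 libraries of the shared block left out, a choice made after seeing the data, calls at 4 h were 246 for PAIR1 and 966 for KIRA9 against induced cells, 161 and 944 against uninduced cells and 230 shared, with fewer libraries tested. The share of higher calls at 4 h moved from 72.3 to 81.7% for PAIR1 and from 51.49 to 60.04% for KIRA9 against induced cells, and from 61.3 to 70.8% for PAIR1 against uninduced cells. The percent retained was 32.6 for PAIR1 over raised and 9.83 for KIRA9 over lowered IDs, with 1 induced library at 24 h to set the scale and choose the IDs. For KIRA9 over raised IDs it was 19.98 without the filter, 17.2 with the block as covariate and 16.6 in the compared groups alone, and over lowered IDs 9.63 with RLE, 10.2 without the filter, 7.69 with the stricter filter and 8.98 in the compared groups alone.

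Leaving out each library gave ranges of 244 to 303 for PAIR1 against induced, 187 to 227 for PAIR1 against KIRA9, 196 to 231 for PAIR1 against uninduced cells, 4 to 7 induction IDs between the compounds and 227 to 349 shared, all at 4 h. The percent retained ranged from 33.7 to 38.3 and 33.4 to 35.6 for PAIR1 and from 17.3 to 21.3 and 9.17 to 11.4 for KIRA9, over raised and lowered IDs, and the score difference at 24 h from 0.86 to 1.30. With the depth, spread and number of libraries at hand, 64.2% of simulated changes of 0.5 log2 units in IDs of at least 1 CPM were recovered for PAIR1 against induced cells at 4 h.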

Other observations

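The tests of the library block in this part were chosen after the result had been seen, and 2 further tests were written down before their own results but after the counts of calls and the overlap with shared controls had been seen. At 24 h 5257 IDs were not called for induction, and some of them still changed with the compounds: against uninduced cells 285 rose and 227 fell with PAIR1, and 294 rose and 404 fell with KIRA9. With separate controls, PAIR1 against uninduced and KIRA9 against induced cells, 318 of these IDs were called in the same direction for both compounds and 3 in opposite directions. These IDs were chosen because induction did not pass the threshold, which does not show that it left them as they were. The choice also keeps the induced and uninduced libraries close to each other in these IDs, so the controls are not fully separate. The number that independent lists would share was not computed here.

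A hypothesis was that PAIR1 and KIRA9 change the same IDs at 4 h beyond what shared control libraries give. With PAIR1 against uninduced and KIRA9 against induced cells, which share no library, 265 IDs were called in the same direction and 4 in opposite directions, where independent lists would give 20.6 and 20.3. The reverse assignment of controls gave 296 and 1, against 24.0 and 24.1. Both compounds may therefore have a common early effect in induced cells, and since 41 IDs were changed by induction at 4 h, this effect need not be a reversal of induction. Whether it passes through IRE1α was not tested, because no uninduced cells received a compound. Induced replicate 3 and uninduced replicate 2 at 4 h belong to the 6 libraries of the shared block, and no compound library at 4 h does. A difference tied to that set can push both contrasts the same way. Of the 49 IDs higher in the set, 0 were called in these contrasts at 4 h, but the shared counts with separate controls were not recomputed without it.

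A further hypothesis was that KIRA9 at 4 h already moves IDs against the direction that induction gives them at 24 h. Of the 1157 IDs called both for KIRA9 against uninduced cells at 4 h and for induction at 24 h, 594 went opposite ways, which is 51.3%, between the bounds of 50% and 60% set beforehand, so the test did not decide. Across IDs the fold changes had r = -0.01 and a Spearman rho of -0.03. The pairs without a bound set beforehand gave 46.1% of 269 for PAIR1 against uninduced cells and 62.8% of 1251 for KIRA9 against induced cells at 4 h. The latter alone passed 60%, so the outcome depended on which 4 h controls were used. In all 6 pairs of contrasts were computed, 2 of them with bounds set beforehand, and the last, PAIR1 and KIRA9 at 24 h, shares its uninduced libraries and was not used.

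The set of 6 libraries was found by looking for IDs whose libraries part by a gap of at least 3 log2 units. Of 10716 IDs with a mean of at least 5 CPM, 14 had such a gap with at least 2 libraries on each side, 11 parted the same 6 libraries from the rest, and no other partition occurred in more than 1 ID. The block was then taken as the 29 IDs of the whole table whose lowest CPM in the 6 libraries was over 2 times the sum of their highest CPM in the other 18 and 0.2, so that its share parts the libraries by choice. The treatment or time does not account for it, since 5 of the 8 groups held libraries of both states, and neither does depth, since 14 of the other 18 libraries had totals within the range of the 6. Another source of RNA, or another passage or subline of the cells in some replicates, may account for it and stays open, because the IDs carry no names here and the labels give no batch. The block's share differed by 1.12 times between the highest and the lowest of the 6 libraries, and no biological explanation was tested.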
